A study of Mus musculus with 6 samples.

How the data were processed

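The series holds 6 dual-colour Agilent whole mouse genome arrays of back skin from C57/BL mice, 2 for each of days 2, 4 and 7 after treatment. Per the labels, total RNA was taken with Isogen, it was made into labelled cRNA, and the cyclosporin A sample carried Cy5 and the ethanol sample Cy3 on every array. Each array is 1 cyclosporin A sample against 1 ethanol sample of the same day. The titles number the replicates of a day 1 and 2, while every sample description reads replicate 1 of 2, and the titles were used. The series text calls the samples biological replicates, and nothing in the labels says that they came from separate animals.

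The deposited scanner files hold the median pixel intensity of each spot in both channels, its local background and processed signals, made with Agilent Feature Extraction 9.1 per the submitters' processing notes. The processed intensity was background-subtracted, spatially detrended and dye-normalized by that software, per the file headers. The deposited value table holds the log10 ratio of Cy5 over Cy3 made by the same software, and it was checked to equal the ratio column of the scanner files (largest difference 0). Its medians were 0, and between 20.8% and 34.9% of its values were exactly 0 per array.

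Each array had 45018 spots, of which 1639 were controls and were left out. Median intensities were corrected with normexp (offset 50) and normalized by loess within each array with limma 3.58.1 in R 4.3.3 (package data.table, version 1.17.8), and log2 ratios of cyclosporin A over ethanol were taken. Spots that the software marked as outliers, 15 to 126 per array, were left out, and 0 spots were saturated. The spots of a probe were averaged, giving 41174 probes. Probes were kept if well above background in either channel on both arrays of at least 1 day (27938 probes). Probes were named through their accession in a RefSeq table of assembly GRCm38.p6 (C57BL/6J), used for names alone. By accession 22951 probes received a symbol, 67 did so by synonym, and 18156 had none. The probe with the highest mean signal stood for each gene. This left 22751 genes, 13473 with a symbol and 9278 without, and 162 of them had a value missing on some array. No genome build of the array is given in the sources used here, and no coordinates were used here.

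The median Cy3 signal was 203 to 277 and the median Cy5 signal 134.5 to 187 per array. The slope of observed on expected log ratios of the spike-in controls was 0.916 to 0.948. The SD of the log2 ratios was 0.262 to 0.441. With 2 arrays per day, the number of arrays limits the precision of every ratio. The arrays of days 2 and 4 lay on 1 slide and those of day 7 on another. An effect of the slide on the ratio of Cy5 to Cy3, or on a single channel, therefore cannot be told apart from day 7. The dyes were not swapped, so that a gene's own dye effect cannot be told apart from treatment within a day.

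One mean per day was fitted to the log2 ratios of all arrays with limma, and each day, the average over days and the 3 differences between days were tested with moderated t statistics (3 residual and 3.763 prior degrees of freedom, prior SD 0.1991). A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The difference between day 7 and day 2 was also tested in each channel alone, on log2 intensities. For these the mean log2 intensity of both channels was given the same distribution across arrays, and the ratios were kept. "At least" folds are given for genes whose dimmer group was not well above background on any of its arrays. They compare the brighter group's mean with the mean, per array, of the higher of the lowest well-above-background signal and the gene's own signal, and without a dye swap they are open to a difference between dyes.

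Gene lists were written before the data were examined, as were the comparisons, the rule for naming genes and all alternatives but those described as chosen later. The 32 lists cover hair shaft keratins, keratin-associated proteins, inner root sheath, anagen follicle regulators, bulge and telogen follicle, follicle growth inhibitors, dermal papilla, melanocytes and pigment, cell cycle, calcineurin pathway and cyclophilins, and calcineurin-NFAT responsive genes. They further cover T cells, macrophages, neutrophils, mast cells, MHC class II and Langerhans cells, interferon-responsive genes, epidermal differentiation, hyperproliferative and basal keratinocytes, adipocytes, sebaceous gland, cholesterol synthesis, and skeletal muscle. The rest are red blood cells, endothelium, fibroblasts and collagen matrix, oxidative and xenobiotic response, unfolded protein response, circadian clock, Schwann cells, and sex-linked check genes. Of 510 genes on any list, 7 are on more than 1 (Bmp6, Fgf18, Nfatc1, Ptgs2, Rcan1, Sfrp1 and Wif1). The 30 lists with at least 5 genes tested were tested as sets against all other genes with camera at a preset inter-gene correlation of 0.01, adjusted over lists, and again with the correlation estimated from the residuals. Counts per list are given from the adjustment over all genes and from one "adjusted over the list alone".

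The genes named were, per day, the 10 highest and 10 lowest log2 ratios among called genes with the same sign on both arrays and a symbol, or where none was called in a direction the 5 with the smallest p. Per list they were up to 4 called members of the largest size, or the 2 with the smallest p, and per difference between days the 5 highest and 5 lowest. Ppia, Ppp3ca, Nfatc1, Rcan1, Shh, Lef1, Wif1, Sfrp1, Fgf5, Fgf7, Bmp4, Vegfa, Foxn1, Hoxc13, Krt35, Krt85, Krt71, Tchh, Tyr, Dct, Mki67, Top2a, Cd3e and Il2 were chosen in any case. Of these Krt85, Tchh and Mki67 had no named probe, and Tyr was not bright enough to be tested.

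Alternatives were no background subtraction, the processed signals, the deposited ratios, median centring, scale normalization between arrays, no filter or a stricter one, spots marked as outliers kept, every probe on its own, an intensity trend with a robust prior, array weights, the replicate number as a block, 2 other thresholds, other scalings of the single channels, the arrays of the compared days alone, and each array left out in turn. The method was tested on simulated data with 22589 genes. It called 64 of 100 genes changed by a log2 ratio of 1 and 98 of 100 changed by 2, with 10 false calls among 172 (5.81%). The simulated noise was independent between genes and drawn from the fitted spread, with no dye effect and no array that stood apart. Its share of false calls is therefore not that of the real calls.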

Results

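Gene expression was measured in the back skin of C57/BL mice treated with cyclosporin A or with ethanol alone. Cyclosporin A is an immunosuppressant that binds cyclophilins and so blocks the phosphatase calcineurin, and increased hair growth is a known side effect of its use. Skin was taken 2, 4 and 7 days after treatment. Each of the 6 dual-colour Agilent arrays set 1 cyclosporin A sample, labelled with Cy5, against 1 ethanol sample of the same day, labelled with Cy3, with 2 arrays per day. All values are log2 ratios of cyclosporin A over ethanol, given as the mean of both arrays of a day (n = 2), unless stated otherwise. Values under median centring hold a shift of all genes, whose median there was 0.39, 0.269 and 0.166 at days 2, 4 and 7. A value that turns above 0 under that setting is therefore not by itself higher than other genes. The standard error (SE) is limma's moderated value, which pools the spread over all 3 days and draws on all genes. It can be smaller than the 2 arrays of a day alone would give. Krt25, for example, stood at 4.47 and 5.92 on the 2 arrays of day 7. The labels call the samples biological replicates without naming the animals, and only the titles number them 1 and 2, so that the p-values measure the spread between these samples. The number of arrays limits the precision. Between 43.5% and 56.5% of the probes were well above background in the ethanol channel and between 59.9% and 68.8% in the cyclosporin A channel, and 22751 genes entered the tests. The transcript Xist, made from the inactive X chromosome of females, was above background in both channels of 6 of 6 arrays, and the Y-linked Ddx3y, Eif2s3y, Kdm5d and Uty on 0 of them.

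The comparison at day 7 asks which transcripts differed in skin 7 days after cyclosporin A. Structural genes of the growing hair follicle had the highest ratios in the data set. Krt71, a keratin of the inner root sheath that encases the growing hair, rose by a log2 ratio of 6.18 (SE 0.14, 72.3-fold, adjusted p = 2.6e-05), with 6.23 and 6.12 on the 2 arrays. The sheath keratins Krt27 (5.72, SE 0.2, 52.8-fold, adjusted p = 8.64e-05) and Krt25 (5.2, SE 0.31, 36.7-fold, adjusted p = 0.000696) rose with it, as did Padi3 (4.42, SE 0.17, 21.4-fold), an enzyme that modifies the sheath protein trichohyalin. Of the 7 inner root sheath genes tested, 5 rose, 5 did so adjusted over the list alone, and the median was 4.42 (camera adjusted p = 2.87e-08, and adjusted p = 0.164 with an estimated correlation).

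Keratins of the hair shaft itself rose too, in 7 of the 8 tested. Krt33a was at least 65-fold higher (log2 6.02, SE 0.27, adjusted p = 0.000163) and Krt34 at least 22.1-fold higher (4.47, SE 0.21, adjusted p = 0.000231), both against an ethanol channel that was not well above background. Krt35 rose 15.9-fold (3.99, SE 0.15) and Krt86 12.3-fold (3.62, SE 0.17). The list had 7 higher adjusted over the list alone and a median of 3.31 (camera adjusted p = 6.23e-13, and adjusted p = 0.164 with an estimated correlation). The keratin-associated proteins, which crosslink keratin filaments in the shaft, lay above 0 in 25 of 26, with a median of 1.97. Of these 18 rose, and 24 did adjusted over the list alone (camera adjusted p = 1.1e-21, and adjusted p = 0.327 with an estimated correlation). Examples were Krtap5-4 (3.85, SE 0.24), Krtap4-16 (at least 13.7-fold higher), Krtap5-1 (3.63, SE 0.17) and Krtap6-1 (3.32, SE 0.37). These genes have close paralogs, and binding of related transcripts to 1 probe was not tested. The 10 highest ratios also held Fbp1, the gluconeogenic enzyme fructose-bisphosphatase (5.03, SE 0.14, 32.7-fold, adjusted p = 4.29e-05), Prr9, a proline-rich protein (4.75, SE 0.21, 26.9-fold), and Gjb2, a gap junction connexin (4.02, SE 0.12, 16.2-fold), of which a dimmer probe gave 1.02. All genes named so far kept their call without any 1 of the 6 arrays. Leaving out an array of day 2 or 4 changes the pooled spread alone and not the ratio at day 7. The call of Krtap6-1 was lost on the scanner software's processed signals (4.09, adjusted p = 0.0518). On those signals and on the deposited ratios the keratin-associated list stood at 3.85. Prr9, Krt86 and Krtap6-1 were well above background on 1 of the 2 arrays in the ethanol channel.

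**Figure D1:**
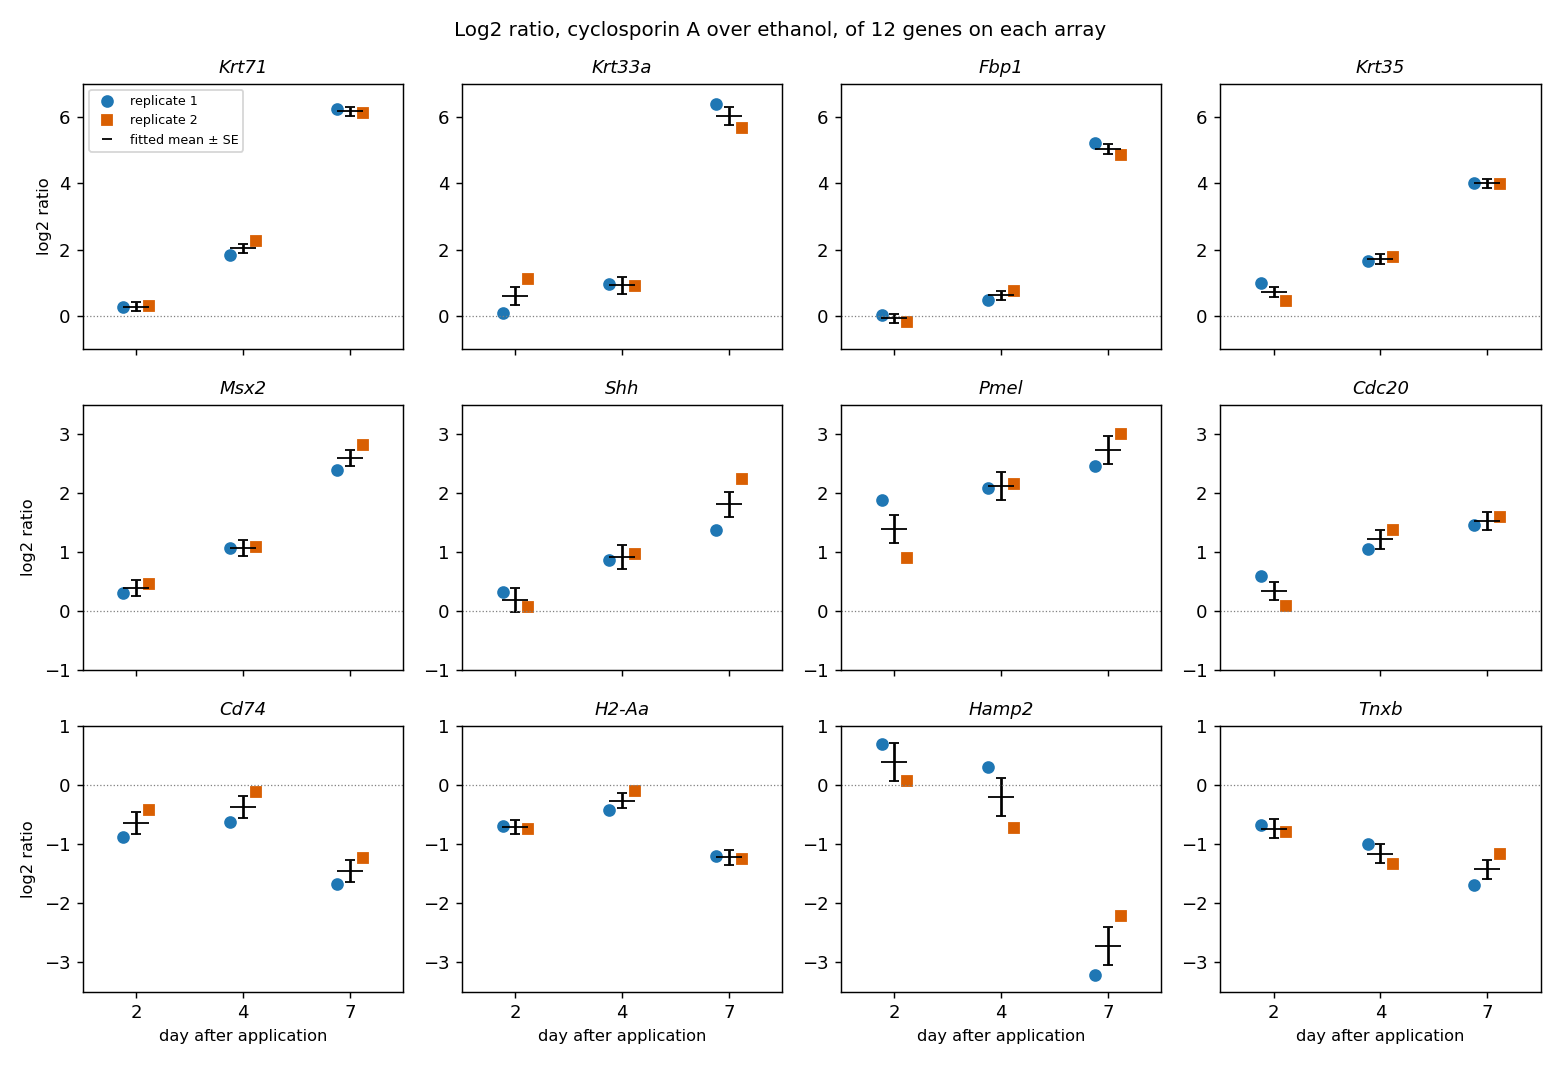
Log2 ratio of cyclosporin A over ethanol (vertical axis) against days after treatment (horizontal axis) for single genes. Points are single arrays, and the line with bars is the fitted mean of both arrays of a day with limma's moderated standard error. Krt71 reached 6.23 and 6.12 at day 7, and H2-Aa lay below 0 on both day 7 arrays.

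Regulators of the growing follicle were also higher as a group at day 7. Msx2, a homeobox factor of the hair matrix, rose 6.08-fold (2.6, SE 0.14, adjusted p = 0.000385), and Shh, the hedgehog ligand that drives follicle growth, was at least 3.51-fold higher (1.81, SE 0.2, adjusted p = 0.0119). Lef1, the nuclear partner of beta-catenin in Wnt signalling, rose 2.97-fold (1.57, SE 0.22, adjusted p = 0.0215), Msx1 2.28-fold (1.19, SE 0.14), and Hoxc13, a regulator of hair keratin genes, at least 1.91-fold (0.93, SE 0.14). Of 17 regulators, 8 rose, 10 did adjusted over the list alone, and the median was 0.63 (camera adjusted p = 2.16e-06, and adjusted p = 0.327 with an estimated correlation). Foxn1, the nude locus factor (-0.24, adjusted p = 0.616), and Bmp4 (-0.03, or 0.33 under median centring, adjusted p = 0.88) did not pass. Over probes well above background in both channels on all arrays the list did not pass (0.56, adjusted p = 0.105). Without day 7 replicate 2, Msx1 reached an adjusted p of 0.0958 and Lef1 0.105. Lef1 was also lost without either day 4 array, and Hoxc13 without any 1 of the 4 arrays of days 4 and 7, with adjusted p up to 0.152. Shh was kept in those fits and lost on the scanner software's processed signals (3.99, adjusted p = 0.0504), where Hoxc13 was lost too. In the ethanol channel Msx2 and Lef1 were well above background on 1 of the 2 arrays.

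Genes of the dermal papilla, the mesenchymal signalling centre at the follicle base, were higher as a group, with 4 of 15 called, 5 adjusted over the list alone and a median of 0.23 (camera adjusted p = 0.0111, and adjusted p = 0.327 with an estimated correlation). The protease gene Corin was at least 2.27-fold higher (1.18, SE 0.11, adjusted p = 0.00601), and Alpl, alkaline phosphatase, rose 2.54-fold (1.34, SE 0.26, adjusted p = 0.0485). Hhip, a hedgehog-binding protein, was at least 2.12-fold higher (1.08, SE 0.16), and Inhba, an activin subunit, rose 2.01-fold (1.01, SE 0.14), while Fgf7 stood at -0.2 (0.1 under median centring, adjusted p = 0.359). The list was lost without day 7 replicate 2 (0.12, adjusted p = 0.119). It was also lost under median centring (0.21, adjusted p = 0.225) and, with a median of -0.14, over probes well above background on all arrays (adjusted p = 0.469). Among inhibitors of follicle growth, Wif1 and Dkk1, both secreted Wnt antagonists, and Fgf5, the signal that ends the growth phase, rose at day 7. Wif1 rose 2.88-fold (1.53, SE 0.26, adjusted p = 0.0358), Dkk1 was at least 2.7-fold higher (1.44, SE 0.25, adjusted p = 0.0367) and Fgf5 at least 2.68-fold (1.42, SE 0.17, adjusted p = 0.0145). The 11 inhibitors had a median of -0.02 (0.17 under median centring), a mean of 0.27 and a set test towards higher values that did not pass (adjusted p = 0.477), with 3 called, and 4 higher and 1 lower adjusted over the list alone. The 14 genes of the bulge and resting follicle did not pass as a set (median 0.07, or -0.04 on the deposited ratios, adjusted p = 0.571). Of these Wif1 and Lgr5, a stem cell receptor (1.06, SE 0.16, adjusted p = 0.0231), rose, 2 did adjusted over the list alone, and Sfrp1, another Wnt antagonist, stood at 0.55 (adjusted p = 0.135). Each of the 8 calls in this paragraph was lost without 1 array or more. The highest adjusted p was 0.0614 for Corin, 0.143 for Inhba, 0.171 for Lgr5 and 0.12 for Fgf5 without day 7 replicate 1. It was 0.256 for Alpl, 0.138 for Hhip, 0.11 for Wif1 and 0.134 for Dkk1 without day 7 replicate 2. On the processed signals Lgr5, Dkk1, Fgf5, Alpl, Hhip and Inhba were lost, and under scale normalization Wif1. On those signals the dermal papilla list stood at 0.5. Alpl in the ethanol channel and Dkk1 in the cyclosporin A channel were well above background on 1 of the 2 arrays.

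Pigment cell genes were higher as a group at day 7. Pmel, which builds the fibrils on which melanin is laid down, rose 6.66-fold (2.74, SE 0.24, adjusted p = 0.00401). The melanin synthesis enzymes Dct (2.37, SE 0.28, adjusted p = 0.0145) and Tyrp1 (2.01, SE 0.2, adjusted p = 0.00776) rose 5.16-fold and 4.03-fold, and the transporter Slc45a2 rose 4.21-fold (2.08, SE 0.16, adjusted p = 0.00245). Of 11 melanocyte genes 7 rose, 8 did adjusted over the list alone, and the median was 1.58 (camera adjusted p = 1.17e-07, and adjusted p = 0.327 with an estimated correlation). Genes of DNA replication and mitosis were above 0 in 37 of 37, with a median of 1.06. Of these 23 rose, and 35 did adjusted over the list alone (camera adjusted p = 1.94e-23, and adjusted p = 0.363 with an estimated correlation). Birc5, survivin, rose 3.44-fold (1.78, SE 0.22) and cyclin Ccna2 3.2-fold (1.68, SE 0.24). So did the mitotic kinase Plk1 2.95-fold (1.56, SE 0.19), the mitotic exit factor Cdc20 2.89-fold (1.53, SE 0.16) and the topoisomerase Top2a 2.51-fold (1.33, SE 0.18, with 0.16 on another probe). The melanocyte list stood at 0.42 over probes well above background on all arrays. Slc45a2 and Tyrp1 were well above background on 1 of the 2 arrays in the ethanol channel. Slc45a2 kept its call without any 1 array, and Birc5, Ccna2 and Top2a were lost on the processed signals. Pmel and Tyrp1 each reached an adjusted p of 0.0518, Dct 0.113, Birc5 0.12, Ccna2 0.157, Plk1 0.102, Cdc20 0.0835 and Top2a 0.105 without day 7 replicate 2.

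**Figure D2:**
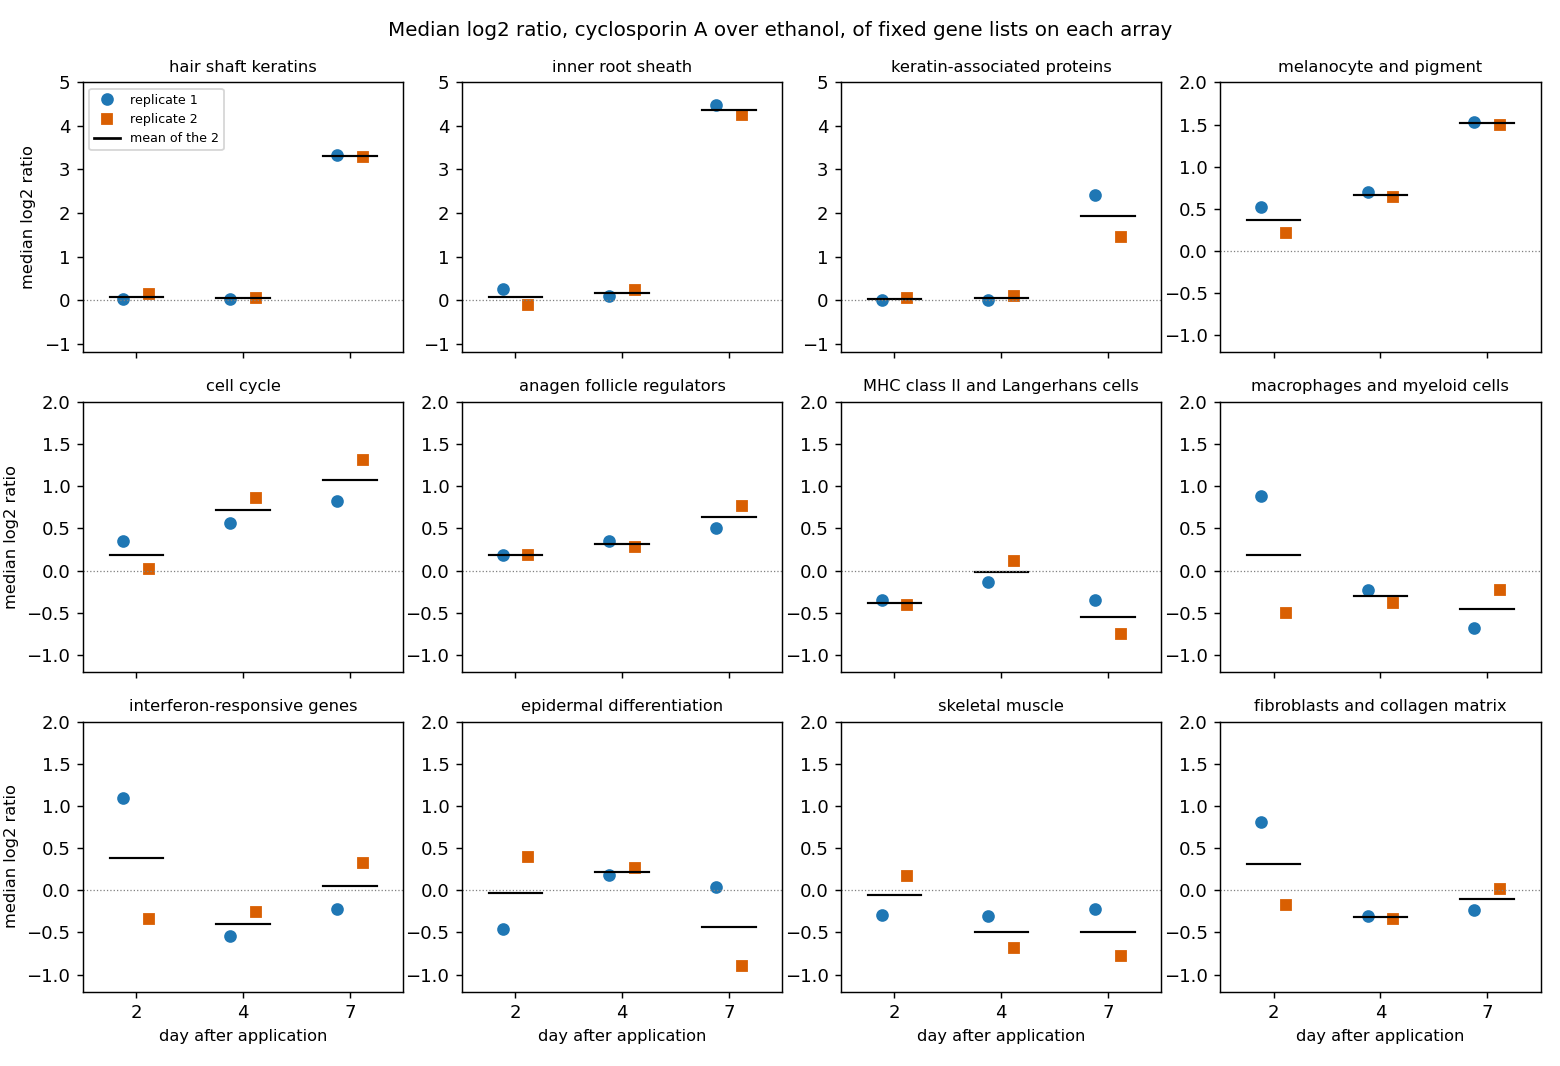
Median log2 ratio of cyclosporin A over ethanol of each gene list (vertical axis) against days after treatment (horizontal axis). Circles are replicate 1, squares replicate 2 and lines the mean of both; the hair shaft keratins stood at 3.34 and 3.29 at day 7, and the cell cycle list lay above 0 on every array.

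Genes of MHC class II and Langerhans cells, which present antigen, were lower as a group at day 7. Cd74, the invariant chain of MHC class II, fell by 1.46 (SE 0.19, 2.75-fold, adjusted p = 0.0169). The class II chains H2-Eb1 (-1.4, SE 0.18, adjusted p = 0.0172) and H2-Aa (-1.23, SE 0.12, adjusted p = 0.00738) fell with it, as did the class I gene H2-D1, which is not on that list (-1.37, SE 0.17, adjusted p = 0.0166). Of the 12 class II and Langerhans cell genes 0 lay above 0, 3 fell, 8 were lower adjusted over the list alone, and the median was -0.55 and -0.07 under median centring (camera adjusted p = 7.23e-07, and adjusted p = 0.327 with an estimated correlation). T cell genes had a median of -0.29 with 0 of 15 called by limma, 6 at an unadjusted p under 0.05 and 5 lower adjusted over the list alone (camera adjusted p = 0.00244, and adjusted p = 0.639 with an estimated correlation). Their lowest p belonged to Cd5 (-0.75, adjusted p = 0.0608), and the T cell receptor subunit Cd3e stood at 0.11 (adjusted p = 0.656). Macrophage genes had a median of -0.39, which turned to 0.17 under median centring, with 0 of 17 called by limma, 5 at an unadjusted p under 0.05 and 2 lower adjusted over the list alone (camera adjusted p = 0.00283, and adjusted p = 0.701 with an estimated correlation). The scavenger receptor Cd163 stood at -1.1 (adjusted p = 0.084) and the Fc receptor Fcgr3 at -1.09 (adjusted p = 0.0915). Under median centring the calls of Cd74 (-0.65, adjusted p = 0.0538) and H2-D1 (-0.49, adjusted p = 0.167) were lost, with H2-Eb1 at -0.7 and H2-Aa at -0.55. All 4 were lost on the processed signals. The T cell list stood at -0.16 under median centring, -0.49 on the deposited ratios, -0.72 on the processed signals and -0.5 without day 7 replicate 1. The MHC class II list stood at -0.35 without day 7 replicate 2 and at -0.75 without replicate 1. Without day 7 replicate 2 the T cell list stood at -0.07 (adjusted p = 0.215), and without day 7 replicate 1 the macrophage list at -0.23 (adjusted p = 0.0565), against -0.68 without replicate 2. Without day 7 replicate 1 the adjusted p was 0.138 for Cd74, 0.136 for H2-Eb1, 0.0725 for H2-Aa and 0.113 for H2-D1.

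Skeletal muscle genes were lower at day 7, with 2 of 20 above 0, 3 called, 6 lower adjusted over the list alone and a median of -0.43, which turned to 0.27 under median centring (camera adjusted p = 1.82e-06, and adjusted p = 0.497 with an estimated correlation). Its 2 arrays stood at -0.22 and -0.78, and without day 7 replicate 2 the adjusted p was 0.0175. Ttn, titin, fell by 1.41 (SE 0.18, adjusted p = 0.0169), and the intermediate filament gene Des fell by 0.88 (SE 0.13, adjusted p = 0.0266). The light chain gene Myl1 fell by 0.86 (SE 0.12, adjusted p = 0.0197) and stood at 0.09 under median centring. Genes of epidermal differentiation had a median of -0.45, which turned to 0.11 under median centring, with 2 of 22 called lower, and 7 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.000128, and adjusted p = 0.651 with an estimated correlation). These were the cornified envelope gene Lce1a1 (-1.25, SE 0.22, adjusted p = 0.0413) and Sbsn, suprabasin (-1.22, SE 0.22, adjusted p = 0.0413). The 2 arrays of that list stood apart, at 0.04 and -0.9, and without day 7 replicate 2 the list was lost (adjusted p = 0.382). Basal keratinocyte genes had a median of -0.27, which turned to 0.45 under median centring, with 1 of 10 called, Lamb3, a laminin 332 chain (-1.29, SE 0.25, adjusted p = 0.0476), and 2 lower adjusted over the list alone (camera adjusted p = 0.0437, and adjusted p = 0.701 with an estimated correlation). That list stood at -0.56 without day 7 replicate 1, and was lost without day 7 replicate 2 (-0.02, adjusted p = 0.467) and without either day 4 array. Among the lowest single genes, Hamp2, a hepcidin, fell by 2.72 (SE 0.32, 6.6-fold, adjusted p = 0.0141) and Angptl7 fell by 1.98 (SE 0.33, adjusted p = 0.034). The serpin Serpinb10 (-1.71, SE 0.22), the adipokine-like C1qtnf3 (-1.44, SE 0.25), the matrix gene Tnxb (-1.43, SE 0.16, with -0.15 on another probe) and the epithelial Clca3a2 (-1.38, SE 0.17) fell as well. Under median centring the calls of Lce1a1 (-0.37, adjusted p = 0.299), Sbsn (-0.25, adjusted p = 0.5), Des (-0.32, adjusted p = 0.222) and Lamb3 (-0.87, adjusted p = 0.0534) were lost. Ttn stood at -0.78, Tnxb at -0.89 and Clca3a2 at -0.73 there. On the processed signals Ttn, Des, Myl1, Lce1a1, Sbsn, Lamb3, Angptl7, C1qtnf3 and Clca3a2 were lost. Each of the 12 calls in this paragraph was lost without 1 array or more. Without day 7 replicate 1 the adjusted p was 0.107 for Hamp2, 0.0869 for Tnxb, 0.152 for Myl1, 0.227 for Lce1a1, 0.224 for Sbsn and 0.282 for Lamb3. Without day 7 replicate 2 it was 0.123 for Ttn, 0.168 for Des, 0.195 for Angptl7, 0.106 for Serpinb10, 0.155 for C1qtnf3 and 0.113 for Clca3a2.

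In all, limma called 680 of the genes tested at day 7, 534 higher and 146 lower, among them Krt71, Msx2, Pmel and H2-Aa, and 327 of them differed at least 2-fold (280 higher and 47 lower). At an unadjusted p under 0.05 there were 5026 genes, where chance alone gives 1138. The count was 147 without day 7 replicate 1, 164 without day 7 replicate 2 and 190 without either day 4 array. Median centring of each array in place of loess called 4966 genes (4387 higher and 579 lower), and the deposited ratios 287 (262 higher and 25 lower). Median centring also moved the median of all genes at day 7 from 0.029 to 0.166. Relative to it the lower lists stood at -0.24 for MHC class II, -0.33 for T cells, 0 for macrophages, 0.1 for muscle, -0.06 for epidermal differentiation and 0.28 for basal keratinocytes. Day 7 was hybridised on a slide of its own, so that an effect of the slide on the ratio of Cy5 to Cy3 cannot be told apart from day there. The dyes were not swapped, so that a gene's own dye effect adds to its ratio.

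Genes of the drug's own targets did not pass at day 7. Of all 22750 genes tested at that day, 5026 had an unadjusted p under 0.05. The unadjusted counts per list at day 7, here and below, are to be read against that share. Of the 16 genes of calcineurin, the NFAT factors it activates and the cyclophilins, limma called 0, with 6 at an unadjusted p under 0.05 and 0 adjusted over the list alone (median -0.08, or 0.34 under median centring, camera adjusted p = 0.277, and adjusted p = 0.581 with an estimated correlation). Ppia, the cyclophilin that binds the drug, stood at 0.18 (adjusted p = 0.63), the calcineurin subunit Ppp3ca at -0.56 (0.14 under median centring, adjusted p = 0.192), Nfatc1 at -0.72 (adjusted p = 0.248), Ppid at 0.62 (adjusted p = 0.0987), and Rcan1, a calcineurin inhibitor that NFAT induces, at -0.14 (0.34 under median centring, adjusted p = 0.479). Of the cytokines and early genes that NFAT drives, 11 of the 17 on the array were bright enough to test, and limma called 0 of them, with 1 at an unadjusted p under 0.05 and 0 adjusted over the list alone (median 0.01, mean 0.02, or -0.07 under median centring, with a set test towards lower values, camera adjusted p = 0.886, and adjusted p = 0.89 with an estimated correlation). The T cell growth factor Il2 stood at 0.17 (-0.11 under median centring, adjusted p = 0.386). Vegfa, an angiogenic factor, stood at -0.2 (0.18 under median centring, adjusted p = 0.677).

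Other cell types and pathways in skin did not pass as sets at day 7. Neutrophil and acute inflammation genes had a median of -0.37 (adjusted p = 0.073, and adjusted p = 0.497 with an estimated correlation), with 0 of 8 called by limma, 4 at an unadjusted p under 0.05 and 4 lower adjusted over the list alone, among them the alarmins S100a9 (-1.56, adjusted p = 0.0874) and S100a8 (-1.16, adjusted p = 0.0936). That list passed towards lower values under 9 of 20 alternatives, among them median centring (-0.23, adjusted p = 0.00399). Keratinocyte genes of wounded or hyperproliferative epidermis had a median of -0.23, or 0.21 under median centring (adjusted p = 0.083), with 0 of 16 called and 3 at an unadjusted p under 0.05. Mast cells had a median of 0.21 (adjusted p = 0.713; 0 of 7 called, 1 unadjusted), and interferon-responsive genes one of 0, or 0.41 under median centring, with a mean of 0.06 and a set test towards lower values (adjusted p = 0.461; 0 of 22 called, 3 unadjusted). Endothelial genes had a median of -0.11, or 0.23 under median centring (adjusted p = 0.256; 0 of 13 called, 2 unadjusted), and Schwann cell genes -0.06, or 0.16 under median centring (adjusted p = 0.345; 0 of 8 called, 2 unadjusted, 1 lower adjusted over the list alone). Fibroblast and collagen genes had a median of -0.05, a mean of 0.02 and a set test towards lower values (adjusted p = 0.632), and 1 of 19, Tnc, a tenascin of growing tissue, rose (0.98, SE 0.17, adjusted p = 0.0377), though not without day 7 replicate 1 (adjusted p = 0.216). In the sebaceous gland list (median -0.14, or 0.4 under median centring, adjusted p = 0.28), the desaturase Fads2 rose (0.92, SE 0.12, adjusted p = 0.0169) and the wax synthase Awat2 fell by 1.07 (SE 0.16, adjusted p = 0.0259), both lost without day 7 replicate 2 (adjusted p of 0.117 and 0.168). Under median centring Awat2 was lost (-0.64, adjusted p = 0.0538), and on the processed signals Awat2 and Tnc were. In the ethanol channel Tnc was well above background on 1 of the 2 arrays. Cholesterol synthesis genes had a median of 0.05 and a mean of 0.02 with a set test towards lower values (adjusted p = 0.632; 0 of 21 called, 3 unadjusted), and genes of the unfolded protein response one of 0 (adjusted p = 0.776; 0 of 13 called, 3 unadjusted). Under median centring the collagen list (0.65, adjusted p = 0.022) and the unfolded protein response (0.57, adjusted p = 0.0212) passed towards higher values. The hyperproliferative list passed without day 7 replicate 1 (-0.4, adjusted p = 0.000809) and the interferon list without day 7 replicate 2 (-0.22, adjusted p = 0.0172), both towards lower values. The 3 red blood cell genes tested had a median of 0.56, 0 called by limma, 1 at an unadjusted p under 0.05 and 1 higher adjusted over the list alone, and were too few for a set test.

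At day 4, cell division and pigment genes already lay higher in cyclosporin A skin. Krt71 was the 1 gene called by limma (2.04, SE 0.14, 4.11-fold, adjusted p = 0.0429), with 1.83 and 2.26 on the 2 arrays, among 3404 genes at an unadjusted p under 0.05. All 37 cell cycle genes lay above 0, with a median of 0.74, 0 called by limma, 32 at an unadjusted p under 0.05 and 32 higher adjusted over the list alone (camera adjusted p = 2.12e-18, and adjusted p = 0.669 with an estimated correlation). Cdc20 stood at 1.22 and the replication helicase gene Mcm7 at 0.86, each with adjusted p = 0.179. All 11 melanocyte genes lay above 0, with a median of 0.67, 0 called, 7 unadjusted and 7 higher adjusted over the list alone (camera adjusted p = 5.41e-07, and adjusted p = 0.669 with an estimated correlation). Among them Pmel stood at 2.13 and Dct at 1.56, each with adjusted p = 0.179. The list's median was 1.21 on the processed signals and the deposited ratios, and 0.14 with the stricter filter. The growing-follicle regulators had a median of 0.37, 0 of 17 called, 6 unadjusted and 5 higher adjusted over the list alone (camera adjusted p = 0.00525, and adjusted p = 0.669 with an estimated correlation). Among them Msx2 stood at 1.08, Shh at 0.93 and Edar, the ectodysplasin receptor, at 0.59, each with adjusted p = 0.179. The inner root sheath list had a median of 0.13, 1 of 7 called and 3 higher adjusted over the list alone (camera adjusted p = 0.0243, and adjusted p = 0.669 with an estimated correlation). The hair shaft keratins (median 0.04, or -0.33 under median centring, adjusted p = 0.451) and keratin-associated proteins (median 0.04, adjusted p = 1) did not pass, with Krt35 at 1.71 (adjusted p = 0.129). Under median centring the keratin-associated proteins passed towards lower values (-0.25, adjusted p = 0.000659). The call of Krt71 was lost without any 1 of the 4 arrays of days 4 and 7, with adjusted p up to 0.7 without day 4 replicate 2, and also under 7 other settings. In 5-array fits limma called 4 genes without either day 2 array and 0 without day 4 replicate 2. Without day 4 replicate 1 the calls of the regulators (0.28) and the inner root sheath list (0.23) were lost, though the median of the latter was higher there. Under median centring both were lost, the regulators at 0.21 (adjusted p = 0.742) and the inner root sheath at 0.59 (adjusted p = 0.454). The regulators stood at 0.62 on the deposited ratios and were lost with the stricter filter (0.24, adjusted p = 0.686), and on the processed signals the inner root sheath at 0.26 (adjusted p = 0.0697).

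Muscle, interferon, collagen, macrophage and endothelial lists were lower at day 4 under loess, and each of their medians turned above 0 under median centring, where the median of all genes itself moved from 0.038 to 0.269. Muscle genes had a median of -0.57 (0.54 under median centring), with 0 of 20 called by limma, 10 at an unadjusted p under 0.05 and 4 lower adjusted over the list alone (camera adjusted p = 5.53e-08, and adjusted p = 0.669 with an estimated correlation). Interferon-responsive genes had a median of -0.37 (0.06 under median centring), with 0 of 22 above 0, 0 called, 5 unadjusted and 0 adjusted over the list alone (camera adjusted p = 4.85e-06, and adjusted p = 0.669 with an estimated correlation). Collagen genes had a median of -0.3 (0.3 under median centring), with 0 of 19 called, 3 unadjusted and 1 lower adjusted over the list alone (camera adjusted p = 0.00189, and adjusted p = 0.669 with an estimated correlation). Macrophage genes had a median of -0.32 (0.36 under median centring; 0 of 17 called, 0 unadjusted, camera adjusted p = 0.0027, and adjusted p = 0.759 with an estimated correlation). Endothelial genes had one of -0.13 (0.32 under median centring; 0 of 13 called, 1 unadjusted, camera adjusted p = 0.0404, and adjusted p = 0.669 with an estimated correlation). Set against the median of all genes under median centring, muscle lay 0.27 higher and interferon genes at -0.21. Single genes with the smallest p below 0, at adjusted p = 0.179 each, were the interferon-induced chemokine Cxcl9 (-1.38), Tnxb (-1.17), the decoy receptor Tnfrsf11b (-1.16), the matricellular Postn (-0.8) and Iffo2 (-0.8). Without day 4 replicate 1 the calls of the collagen list (-0.34) and the endothelial list (-0.07) were lost. That of the endothelial list was also lost without replicate 2 (-0.16). The muscle list stood at -0.31 without day 4 replicate 2 and at -0.68 without replicate 1.

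At day 2, pigment genes lay higher and MHC class II genes lower, with no single gene called. The smallest adjusted p of limma was 0.471 and 2202 genes had an unadjusted p under 0.05, where chance gives 1138. Melanocyte genes had a median of 0.37, 10 of 11 above 0, 6 at an unadjusted p under 0.05 and 6 higher adjusted over the list alone (camera adjusted p = 0.000893, and adjusted p = 0.906 with an estimated correlation), with Pmel at 1.39 (SE 0.24; 1.89 and 0.9 on the 2 arrays). MHC class II genes had a median of -0.34, which turned to 0.39 under median centring, with 4 of 12 unadjusted and 3 lower adjusted over the list alone (camera adjusted p = 0.000222, and adjusted p = 0.906 with an estimated correlation). Cell cycle genes had a median of 0.17 (3 of 37 unadjusted, 0 adjusted over the list alone, camera adjusted p = 0.0301, and adjusted p = 0.906 with an estimated correlation). Collagen genes had a median of 0.28, or 1.07 under median centring (3 of 19 unadjusted, 1 higher adjusted over the list alone, camera adjusted p = 0.0464, and adjusted p = 0.906 with an estimated correlation). Cholesterol synthesis genes had a median of -0.28, or 0.38 under median centring (3 of 21 unadjusted, 0 adjusted over the list alone, camera adjusted p = 0.000222, and adjusted p = 0.906 with an estimated correlation). Endothelial genes had one of -0.14, or 0.52 under median centring (0 of 13 unadjusted, camera adjusted p = 0.0301, and adjusted p = 0.906 with an estimated correlation). With the stricter filter the melanocyte list stood at 0.16 and the cell cycle list at 0.26. Median centring moved the median of all genes at day 2 from 0.036 to 0.39, and relative to it MHC class II stood at 0, cholesterol synthesis at -0.01 and endothelium at 0.13. The genes with the smallest p were Cetn4 (0.76), Pmel, Col24a1 (0.75), Cplx3 (0.69) and Olfr788 (0.68) above 0, and Cxcl9 (-1.49, SE 0.16), C1qtnf3 (-1.68), Pyy (-1.48), Mmp2 (-0.83) and Il25 (-0.72) below 0, each with adjusted p = 0.471. In the ethanol channel Cetn4, Col24a1, Cplx3 and Olfr788 were well above background on 0 arrays of day 2. The follicle keratins Krt71 (0.27, adjusted p = 0.574) and Krt35 (0.72, adjusted p = 0.471) did not pass.

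The day 2 arrays stood apart from each other. Their ratios correlated at Pearson r = 0.01 across genes, against 0.43 between the day 4 arrays and 0.59 between the day 7 arrays (genes are not independent replicates). Interferon-responsive genes had a median of 1.1 on day 2 replicate 1 and -0.34 on replicate 2, macrophage genes 0.88 and -0.5, and collagen genes 0.81 and -0.18. Without day 2 replicate 1 the collagen list passed in the other direction (-0.18, adjusted p = 0.0291), with cholesterol synthesis at 0.06 (adjusted p = 0.656), the cell cycle list at 0.02 (adjusted p = 0.657) and the melanocyte list at 0.21 (adjusted p = 0.083). Under median centring the melanocyte list (0.58, adjusted p = 0.677) and the cell cycle list (0.61, adjusted p = 0.46) were lost. The collagen list was lost on the processed signals (0.23, adjusted p = 0.124), and without day 7 replicate 1 (adjusted p = 0.056) or replicate 2 (adjusted p = 0.0642). The MHC class II list kept its call without any 1 array (adjusted p up to 0.0262). The endothelial list was lost without day 2 replicate 2 (-0.03, adjusted p = 0.907), with collagen at 0.81, the cell cycle at 0.35 and cholesterol synthesis at -0.49. The endothelial list stood at -0.31 without replicate 1. Without the day 2 arrays, a fit chosen after seeing the data, limma called 4 genes at day 4 and 688 at day 7, of which 572 were among the 680.

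The tests between days ask whether the ratio changed with time. A dye effect that shifts every array's log2 ratio by the same amount cancels in them. It need not cancel where a gene is too dim on 1 of the days for the effect to show. A slide effect shared by both channels cancels within each array's ratio. An effect of the slide on the ratio of Cy5 to Cy3 does not cancel where day 7 is compared, since its arrays lay on a slide of their own. Between day 2 and day 7 the ratio of 60 genes rose and that of 0 fell by limma, with 1394 at an unadjusted p under 0.05, where chance gives 1137. Krt71 rose by 5.9 (SE 0.19, adjusted p = 0.000245), Krt27 by 5.72, Krt33a by 5.42, Fbp1 by 5.1 (SE 0.2, adjusted p = 0.000402) and Krt25 by 4.95. In the ethanol channel at day 2, Krt71, Krt27, Krt33a and Krt25 were well above background on 0 arrays. The sizes of their differences and their order are therefore uncertain. Between day 4 and day 7 the ratio rose in 46 genes, all among the 60, and fell in 0 (1017 unadjusted, chance 1138). The highest were Krt33a (5.1), Krt27 (5.02), Prr9 (4.78), Fbp1 (4.4) and Padi3 (4.39). Of the lists, the hair shaft keratins were higher at day 7 than at day 2 by a median of 3.11, with 6 of 8 called and 7 adjusted over the list alone (camera adjusted p = 3.3e-23, and adjusted p = 0.0692 with an estimated correlation). The inner root sheath was higher by 4.41, with 5 of 7 called and 5 adjusted over the list alone (camera adjusted p = 2.3e-17, and adjusted p = 0.0692 with an estimated correlation). The keratin-associated proteins were higher by 1.85, with 7 of 26 called and 23 adjusted over the list alone (camera adjusted p = 3.8e-37, and adjusted p = 0.271 with an estimated correlation). Between day 2 and day 4, which share a slide, limma called 0 genes, with 510 at an unadjusted p under 0.05, fewer than the 1138 that chance gives. The cell cycle list was higher at day 4 than at day 2 by a median of 0.52, above 0 in 37 of 37, with 0 called, 11 unadjusted and 0 adjusted over the list alone (camera adjusted p = 5.92e-20, and adjusted p = 0.575 with an estimated correlation). Between day 2 and day 7 the count was 29 without day 2 replicate 1, 30 without day 2 replicate 2, 28 without either day 4 array and 48 or 88 without either day 7 array. Between day 4 and day 7 it was 17 without either day 4 array and 78 without day 7 replicate 2. Krt25 lost its call between day 2 and day 7 without day 2 replicate 2 (adjusted p = 0.066) and without any 1 other array of days 2 and 4, and Krt33a between day 4 and day 7 without day 4 replicate 2 (adjusted p = 0.104) or replicate 1.

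The single channels ask in which channel the signal of the follicle genes changed between day 2 and day 7. These days lay on different slides, and in a single channel a slide effect cannot be told apart from a change with time. The signal of inner root sheath keratins rose in both channels. Krt71 rose by 9.66 (SE 0.21, adjusted p = 2.11e-06) in the cyclosporin A channel and by 3.75 (SE 0.22, at least 13.5-fold, adjusted p = 0.00165) in the ethanol channel, where it was not well above background at day 2. Krt25 rose by 8.33 and 3.38 (at least 10.4-fold), Krt27 by 8.03 and 2.3 (at least 4.93-fold), and Krt35 by 6 (64-fold) and 2.72 (6.59-fold, adjusted p = 0.00127). Krt33a (5.82), Fbp1 (5.73), Prr9 (5.16), Padi3 (5.05) and Msx2 (2.51) rose in the cyclosporin A channel, while their ethanol values of 0.4, 0.63, 0.35, 0.63 and 0.29 did not pass. In the ethanol channel Krt33a was well above background on 0 arrays of both days and Msx2 on 1 array of day 7, so that a rise there may be hidden for these genes. In the cyclosporin A channel 7 of 8 hair shaft keratins (median 4.08), 5 of 7 inner root sheath genes (median 5.05), 9 of 26 keratin-associated proteins (median 2.1), 11 of 37 cell cycle genes (median 1.05) and 4 of 11 melanocyte genes (median 1.05) rose. In the ethanol channel 1, 3, 0, 0 and 0 of them did, with medians of 0.65, 0.63, 0.17, 0.25 and 0.09. In total limma called 211 genes in the cyclosporin A channel (203 higher and 8 lower) and 8 in the ethanol channel (7 higher and 1 lower, the glutathione transferase Gsta3 at -1.38, adjusted p = 0.0429, named after its values were seen), with 3155 and 2572 at an unadjusted p under 0.05. The cyclosporin A count was 105 without day 2 replicate 1, 47 without day 2 replicate 2 and 866 without day 7 replicate 2. The ethanol count was 30 without day 2 replicate 2, 16 without day 7 replicate 1 and 249 without day 7 replicate 2.

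**Figure D3:**
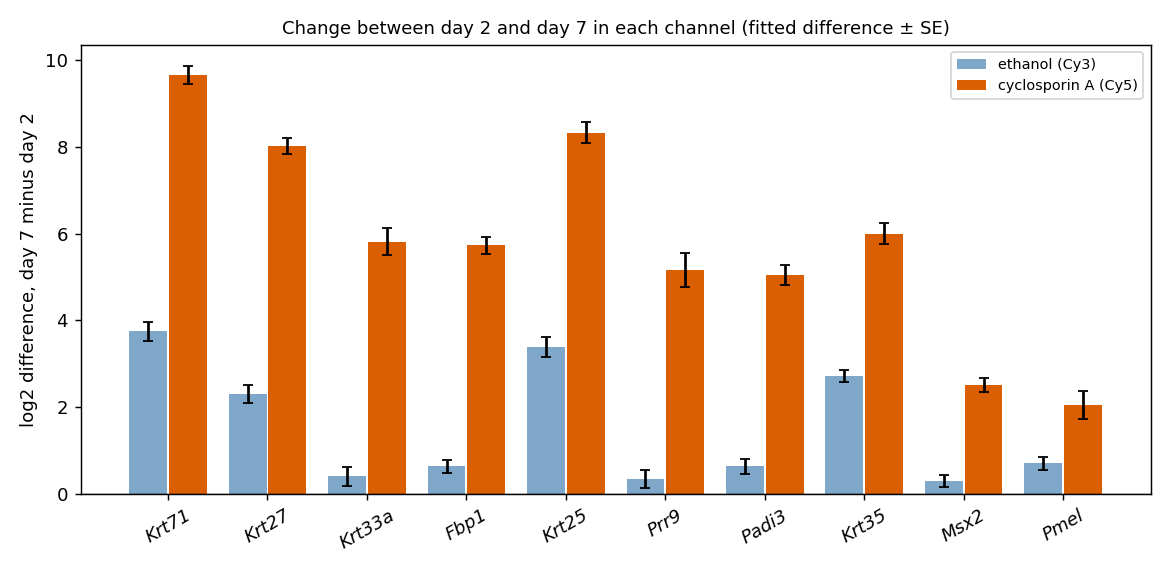
Difference in log2 intensity between day 7 and day 2 (vertical axis) within the ethanol channel (Cy3) and the cyclosporin A channel (Cy5) for single genes (horizontal axis). Bars are differences of day means from 2 arrays each, with limma's moderated standard errors, and the 2 days lay on different slides. Krt71 differed by 3.75 in the ethanol channel and by 9.66 in the cyclosporin A channel.

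Averaged over the 3 days, cell division genes were the group with the most members called, with 32 of 37 higher, 34 adjusted over the list alone and a median of 0.69 (camera adjusted p = 1.14e-16, and adjusted p = 0.482 with an estimated correlation). Of the melanocyte genes 7 of 11 rose (median 0.72, 8 adjusted over the list alone, camera adjusted p = 2.72e-06, and adjusted p = 0.482 with an estimated correlation). Of the muscle genes 7 of 20 fell (median -0.41, 10 adjusted over the list alone, camera adjusted p = 1.98e-06, and adjusted p = 0.482 with an estimated correlation). In all limma called 2974 genes, 2199 higher and 775 lower, of which 73 differed at least 2-fold (66 higher and 7 lower). Under median centring the median turned to 0.64 for the muscle genes, and the melanocyte list stood at 0.58 (adjusted p = 0.0573). Without day 7 replicate 2 the muscle list stood at -0.23 (adjusted p = 0.000145). A constant dye effect enters this average in full. The count was 27 without day 4 replicate 2, 244 without day 4 replicate 1, 593 without day 7 replicate 2, 851 without day 7 replicate 1, 1328 without day 2 replicate 1 and 1504 without day 2 replicate 2. Of the genes higher at day 7, 465 of 534 (87.1%) lay above 0 on both day 4 arrays and 356 (66.7%) on both day 2 arrays, against 38.6% and 33% of all genes. Of the 146 lower, 126 (86.3%) lay below 0 on both day 4 arrays and 113 (77.4%) on both day 2 arrays, against 27.4% and 22% of all genes. A constant dye effect gives the same sign on every day, so that these shares cannot tell an early effect of the drug from dye. Of the 680 genes called at day 7, 60 differed between day 7 and day 2.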

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

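The tests of technical and biological explanations in this part were chosen only after the result was seen, except the sign changes of the arrays, which were planned. Leaving out arrays for the lists' differences between days was also chosen after seeing the data.

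The ratio of cyclosporin A over ethanol differed between days, where day 7 cannot be told apart from an effect of its slide on the ratio. Between day 2 and day 4, which share a slide, limma called 0 genes. Between day 2 and day 7 the ratio differed in 60 genes by limma's test of the difference, and between day 4 and day 7 in 46, all among the 60. Against day 2 the highest were Krt71 (5.9), Krt27 (5.72), Krt33a (5.42), Fbp1 (5.1) and Krt25 (4.95). Krt71, Krt27, Krt33a and Krt25 were not well above background in the ethanol channel at day 2, so that these sizes and their order are uncertain. Against day 4 the highest were Krt33a (5.1), Krt27 (5.02), Prr9 (4.78), Fbp1 (4.4) and Padi3 (4.39). Without day 2 replicate 2, Krt25 reached an adjusted p of 0.066 against day 2, and it was also lost without day 2 replicate 1 and without either day 4 array. Without day 4 replicate 2, Krt33a reached 0.104 against day 4, and 0.089 without replicate 1. The counts were 29, 30 and 28 against day 2 without day 2 replicate 1, day 2 replicate 2 and either day 4 array, and 17 against day 4 without either day 4 array; both were higher without day 7 replicate 2, at 88 and 78.

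Of the 30 lists tested as sets, 14 differed between day 2 and day 4, 15 between day 2 and day 7 and 16 between day 4 and day 7 at the preset correlation, and 0 in each with an estimated correlation, where 1, 4 and 4 had an unadjusted p under 0.05 in camera. Between day 4 and day 7 MHC class II genes moved by a median of -0.67 (camera adjusted p = 1.46e-09, and adjusted p = 0.251 with an estimated correlation) and epidermal differentiation genes by -0.73 (camera adjusted p = 3.41e-09, and adjusted p = 0.531 with an estimated correlation). Between day 2 and day 4 collagen genes moved by -0.62 (camera adjusted p = 1.55e-09, and adjusted p = 0.575 with an estimated correlation), interferon-responsive genes by -0.86 (camera adjusted p = 2.2e-07, and adjusted p = 0.585 with an estimated correlation) and macrophage genes by -0.44 (camera adjusted p = 0.000381, and adjusted p = 0.585 with an estimated correlation). In these 5 lists limma called 0 genes for those differences, with 7, 9, 4, 1 and 0 at an unadjusted p under 0.05, and 3, 0, 0, 0 and 0 adjusted over the list alone. Without day 2 replicate 1 the collagen genes moved by -0.16 (adjusted p = 0.123) and the interferon-responsive genes by -0.06 (adjusted p = 0.969) between day 2 and day 4, and the macrophage genes turned to 0.23 (adjusted p = 0.0109). Without day 2 replicate 2 these lists moved by -1.19, -1.5 and -1.17. Without day 4 replicate 1 the interferon-responsive genes moved by -0.56 (adjusted p = 0.0091). The epidermal differentiation genes moved by -0.39 between day 4 and day 7 without day 7 replicate 2 (adjusted p = 0.0412), and by -1.17 without day 7 replicate 1.

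The first pattern weighed is the higher follicle structural genes at day 7. A dye effect that shifts every array's log2 ratio by the same amount would leave no difference between days. The median difference between day 7 and day 2 over the 41 tested members of the hair shaft, keratin-associated and inner root sheath lists was 2.17. It was above 0 in 39 of 41, against a median standard error of 0.3. Background correction with an offset draws the ratios of dim genes towards 0, however, so that a dye effect may show only once a gene is bright. Krt71, Krt27, Krt25, Krt33a and Krt34 were not well above background in the ethanol channel at day 2. For such genes the test cannot exclude dye. An effect of the slide on the Cy5 to Cy3 ratio of these genes stays open. Within the slide that holds days 2 and 4 the same members differed by 0.04 (26 of 41 above 0), which such a slide effect and a change after day 4 would both give. A candidate explanation is a larger share of growing follicles in cyclosporin A skin, which would also raise the cell cycle, melanocyte and follicle regulator lists. Their 65 members had a median of 0.98 at day 7, above 0 in 60. These lists had been seen to be higher before the test was chosen and the share of follicles in growth was not analysed here, so that this stays a hypothesis.

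The second pattern is the higher interferon, macrophage and collagen genes on day 2 replicate 1. An exchange of its samples stays open: the median correlation of its ratios with the 4 arrays of days 4 and 7 was 0.24, but a dye effect constant over arrays could hold it above 0 in any case. An ethanol sample that stands apart would leave the cyclosporin A channel unmoved, but that channel deviated by a median of 0.72 from the other 5 arrays, above 0 in 55 of 58 members (SD 0.47). The ethanol channel deviated by -0.34, above 0 in 8 of 58, so that both channels of that array stood apart. More immune and connective tissue cells in that cyclosporin A sample would also raise other immune lists. Their median on the array was -0.19 with an SD of 0.42 over 34 members, so that it may still hold for some cell types and stays open.

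The third pattern is the 2974 genes called in the average over days. Of the 32 ways to give signs to the 6 arrays, 1 called as many genes, the real one. The highest of the others called 473, with the sign of day 2 replicate 2 turned. With 32 ways the test is coarse, and a dye effect shared by all arrays also favours the real signs. The real signs thus stood out from the others, which does not tell treatment from dye. A dye effect that is constant over arrays would also give a call in the average. Of the called genes, 58 differed between day 7 and day 2, which such an effect cannot give, and for the rest it cannot be told apart from treatment, since the dyes were not swapped.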

How the results depend on the processing

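The alternatives were chosen before the data were examined, except the fit without the day 2 arrays and the alternatives for lists in the average and between days, which were chosen after seeing the data. Where a value moved, the cause was not tested. A fit without 1 array leaves a day with 1 array and assumes that it varies like the others. For the ratio of another day it changes the pooled spread alone. There, leaving out either array of a day gives in effect the same fit and is not a separate check. The slide as a block was not run, since day 7 has a slide of its own. Signal over background limits what the ethanol channel shows, where Krt33a and Krt34 were not well above background.

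Of the genes named at day 7, 1616 values over all alternatives kept their direction and side of the threshold, 198 lost their call, 29 gained one, 23 moved and 1 turned direction. For lists at day 7 the numbers were 555, 33, 17, 17 and 3. A list turns here if its set test, which compares it with all other genes, changes direction and passes before or after. Of 56 named genes called at day 7, 35 were lost without day 7 replicate 2, 27 without day 7 replicate 1, 21 without either day 4 array, 27 on the processed signals, 20 on the deposited ratios, 13 under scale normalization and 7 under median centring (besides Myl1, which turned).

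At day 2, limma called 8722 genes (8027 higher and 695 lower) under median centring, and 0 to 1 with 1 array left out. At day 4, where it called 1, it called 0 with no background subtraction, on the processed signals, under scale normalization, with no filter, with the stricter filter and at an adjusted p under 0.01, 5584 under median centring (5260 higher and 324 lower), 5 from the day 4 arrays alone, 4 without the day 2 arrays, and 0 to 4 with 1 array left out. At day 7, where it called 680 (78.5% higher), it called 221 on the processed signals (86.9% higher), 4966 under median centring (88.3% higher, 546 shared), 317 under scale normalization, 287 on the deposited ratios (91.3% higher), 365 with the stricter filter, 103 at an adjusted p under 0.01, 327 of at least 2-fold, 409 from the day 7 arrays alone, and 147 to 688 with 1 array left out. In the average, where it called 2974 (73.9% higher), it called 1191 on the processed signals, 13594 under median centring, 1680 on the deposited ratios, 5419 with no filter (56.9% higher), 1097 with the stricter filter (60.7% higher), 141 at an adjusted p under 0.01, 73 of at least 2-fold, and 27 to 1504 with 1 array left out. Median centring moved the median of all genes from 0.036 to 0.39 at day 2, from 0.038 to 0.269 at day 4, from 0.029 to 0.166 at day 7 and from 0.033 to 0.279 in the average.

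The ratio differed in 0 to 1 genes between day 2 and day 4 with 1 array left out. For day 7 against day 2, where limma called 60, it called 39 with no background subtraction, 11 with the stricter filter, 32 at an adjusted p under 0.01, 28 from the arrays of those days alone, and 28 to 88 with 1 array left out. For day 7 against day 4, where it called 46, it called 26 with no background subtraction, 8 with the stricter filter, 25 at an adjusted p under 0.01, and 17 to 78 with 1 array left out. In the ethanol channel 7 to 249 genes were called with 1 array left out. In the cyclosporin A channel, where 211 were called, 326 were under 75th percentile scaling and 47 to 866 with 1 array left out. Krt27 lost its call between day 2 and day 7 on the processed signals (5.69, adjusted p = 0.106) and between day 4 and day 7 (4.6, adjusted p = 0.266).

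With the replicate block, limma called 0 genes at day 4, 330 at day 7 (272 higher and 58 lower), 1268 in the average, 39 between day 2 and day 7 and 66 in the cyclosporin A channel. Of the 56 named calls at day 7, 10 were lost with it. The deviations of same-numbered arrays correlated at 0.01 between days 2 and 4, -0.28 between days 2 and 7 and -0.02 between days 4 and 7. Between days 2 and 7, arrays with different numbers were the more alike. The ratios of day 2 replicate 1 correlated at 0.45 with day 7 replicate 2 and at 0.22 with replicate 1. Those of day 2 replicate 2 correlated at 0.13 and 0.26 with the same arrays.

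At day 2, 6 lists passed, against 10 on the processed signals, 0 with an estimated correlation and 5 to 14 with 1 array left out. At day 4, 9 passed, against 0 with an estimated correlation and 5 to 10 with 1 array left out. At day 7, 13 passed, against 8 with the stricter filter, 0 with an estimated correlation and 10 to 15 with 1 array left out. Over all alternatives, list medians at day 7 ranged from 3.04 to 4.19 for hair shaft keratins (adjusted p 2.73e-14 to 0.164), 4.05 to 5.71 for the inner root sheath (2.48e-09 to 0.164), 1.44 to 3.85 for keratin-associated proteins (1.86e-34 to 0.327), 0.83 to 1.48 for the cell cycle (7.64e-33 to 0.363), 0.42 to 2.37 for melanocytes (8.74e-09 to 0.327), 0.51 to 0.79 for follicle regulators (8.32e-08 to 0.327) and -0.14 to 0.5 for the dermal papilla (0.00163 to 0.469). They ranged from -0.75 to -0.07 for MHC class II (1.91e-09 to 0.327), -0.72 to -0.07 for T cells (1.92e-05 to 0.639), -0.68 to 0.17 for macrophages (6.04e-05 to 0.701), -0.78 to 0.27 for muscle (2.4e-10 to 0.871), -0.9 to 0.11 for epidermal differentiation (4.72e-09 to 0.719) and -0.56 to 0.45 for basal keratinocytes (0.00612 to 0.701).

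In that sense, directions turned under median centring at day 2 for MHC class II (0.39), cholesterol synthesis (0.38), muscle (0.92) and endothelium (0.52). At day 4 they turned for keratin-associated proteins (-0.25), MHC class II (0.59), muscle (0.54), endothelium (0.32) and collagen (0.3), and at day 7 for basal keratinocytes (0.45), collagen (0.65) and the unfolded protein response (0.57). Lists that passed with it and not under loess, with a set test that did not turn, were keratin-associated proteins (-0.3), NFAT-responsive genes (-0.17) and the unfolded protein response (0.85) at day 2, epidermal differentiation (1.05) and the unfolded protein response (0.8) at day 4, and neutrophils (-0.23), adipocytes (1) and oxidative response (0.57) at day 7. Of named genes called before or after, Rcan1 (0.48), Plin2 (0.73), Postn (0.47) and Ppp3ca (0.79) at day 2, H2-Aa (0.52) at day 4 and Myl1 (0.09) at day 7 changed sign. These values hold the shift of all genes to 0.39, 0.269 and 0.166, and Myl1 lies below it. The medians of macrophages (0.36) and interferon-responsive genes (0.06) at day 4, and of macrophages (0.17), muscle (0.27) and epidermal differentiation (0.11) at day 7, also changed sign, while their set tests stayed lower and no longer passed. That of keratin-associated proteins at day 2 changed sign as well. In the other lists whose median changed sign, no set test passed before or after. Without day 2 replicate 1 the set test turned for the cell cycle (0.02, and 0.35 without replicate 2), macrophages (-0.5 and 0.88), interferon-responsive genes (-0.34 and 1.1), epidermal differentiation (0.39 and -0.46), basal keratinocytes (0.3 and -0.45) and collagen (-0.18 and 0.81) at day 2. Without day 2 replicate 2 it turned for endothelium (-0.03, and -0.31 without replicate 1).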

Other observations

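No hypothesis beyond those above was tested in this part, and the values come from the planned comparisons, with arrays left out of the average chosen after seeing the data.

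Among the genes of oxidative and xenobiotic response, the metallothionein Mt2 stood at 0.11, 1.38 and 1.79 at days 2, 4 and 7 (adjusted p = 0.0583 at day 7). Mt1 stood at 0.71 at day 4 (adjusted p = 0.241), while the glutathione transferase Gstm1 stood at -0.8 at day 7 (0.01 under median centring, adjusted p = 0.0728). Of the 14 genes limma called 0 at day 7, with 4 at an unadjusted p under 0.05, and 2 higher and 2 lower adjusted over the list alone (median 0.19, camera adjusted p = 0.117, and adjusted p = 0.481 with an estimated correlation). The list passed under median centring (0.57, adjusted p = 0.0212) and with no filter (adjusted p = 0.0394). Adipocyte genes, whose tissue thickens under growing hair, had a median of 0.26 at day 7, above 0 in 11 of 14, with 0 called by limma, 4 at an unadjusted p under 0.05 and 0 adjusted over the list alone (camera adjusted p = 0.133, and adjusted p = 0.701 with an estimated correlation). It passed under median centring (1, adjusted p = 0.00771), from the day 7 arrays alone (adjusted p = 0.0238) and without day 7 replicate 1 (0.43, adjusted p = 0.0136). The adipocyte list stood at 0.19 and -0.44 on the arrays of day 2, 0.33 and -0.3 on those of day 4, and 0.06 and 0.43 on those of day 7. Between day 2 and day 7 its median moved by 0.04 in the cyclosporin A channel and by -0.47 in the ethanol channel. The lipid carrier Fabp4 stood at 0.82 (adjusted p = 0.112) and the fatty acid transporter Cd36 at 0.44 (adjusted p = 0.144).

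Circadian clock genes lay slightly below 0 at day 7, with a median of -0.2 that turned to 0.15 under median centring, against a median of all genes of 0.166 there. Of the 12 genes limma called 0, with 4 at an unadjusted p under 0.05 and 0 adjusted over the list alone (camera adjusted p = 0.122, and adjusted p = 0.581 with an estimated correlation). The list passed without day 7 replicate 1 (-0.35, adjusted p = 0.0487). The repressor Nr1d1 stood at -0.68 (adjusted p = 0.106) and Cry2 at -0.39 (adjusted p = 0.127). At day 2 the list stood at -0.1, or 0.42 under median centring (camera adjusted p = 0.0634), and passed under 9 of 20 alternatives, among them the fit without day 2 replicate 2 (-0.21, adjusted p = 0.0104). At day 4 Per1 stood at -1.11 and Per3 at -0.83, each with adjusted p = 0.179. In the average over days the list had a median of -0.16, or 0.27 under median centring, with 3 called lower and 1 higher, and 3 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.0352, and adjusted p = 0.482 with an estimated correlation). It was lost without day 2 replicate 1 (-0.15, adjusted p = 0.097) and without day 7 replicate 2 (-0.12, adjusted p = 0.0947).

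Among early NFAT and inflammation genes, Csf2 stood at 0.86 and Il1b at 0.9 at day 4, each with adjusted p = 0.179. The red blood cell gene Hba-a1 stood at 0.68 at day 7 (adjusted p = 0.229), and Xist at -0.17 (0.13 under median centring), the 1 gene of the sex-linked list that was tested, not called by limma and not at an unadjusted p under 0.05.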
